A study of Sus scrofa with 2 samples.

How the data were processed

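Total RNA was taken from backfat of 3 intact and 3 castrated male Huainan pigs aged 300 days, per the labels' protocols. Ribosomal RNA was removed with a Ribo-Zero kit and a strand-specific library kit (NEBNext Ultra Directional) was used before sequencing on an Illumina HiSeq instrument; the protocol also names an Illumina TruSeq RNA kit. The series lists 1 sample per group, and the tables hold 1 value per group. How the 3 pigs of a group became 1 value is not given in the sources used here, so neither pooling of RNA nor averaging can be assumed.

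The submitters' processing notes name TopHat2, Cufflinks and the genome build Sscrofa10.2, with no role, order or version. Per the file headers, the mRNA and lncRNA tables give FPKM per transcript for each group as the authors computed it. The authors also deposited a log2 fold change, which equals log2 of the FPKM ratio without a pseudocount and is infinite where a group is at 0. The p-values and q-values in those tables are the authors' own, and the number of transcripts they were adjusted over is not given in the sources used here. All q-values listed lie below 0.05 (the largest was 0.0499) and the smallest absolute log2 fold change was 1.15, so the tables hold called transcripts and leave out the others. The lncRNA table adds neighbouring target genes assigned by the authors, over 48 lines for 18 transcripts.

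Per the file headers, the circRNA table gives read counts per circRNA for each group as deposited. Its other value columns, headed as TPM, equal the count times 1000000 divided by the column total and are thus RPM, reads per 1000000 circRNA reads, as the authors deposited them. The circRNA caller is not given in the sources used here. The totals were 46409 reads for the castrated and 43589 for the intact group, so 1 read was worth 21.5 and 22.9 RPM. The depth behind the FPKM values is unknown, and no interval was computed for them.

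Both groups entered each comparison as castrated against intact. With 1 value per group no test between groups was made, no own p-value for a difference between the groups is given, and a size rule described changes: at least 2-fold on the log2(FPKM + 1) scale with at least 1 FPKM in the higher group. For circRNAs the pseudocount was the smallest RPM above 0 (43.1) and the level minimum was the median of the higher group's RPM (64.6). Ratios of circRNA shares have exact (Clopper-Pearson) 95% intervals conditional on the summed reads, and a value of 0 reads was given a floor of 3 counts, 64.6 RPM in the castrated and 68.8 RPM in the intact group. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

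Gene symbols came from the mRNA table and from a RefSeq gene table of another assembly, used for names only: 87.6% of lines matched it by gene ID (1946 of 2266 gene IDs), and 157 lines with a LOC identifier were given a symbol this way. A LOC identifier without a symbol was treated as no symbol, a choice made after the data were seen. A gene's value is the sum of FPKM over its listed transcripts and not its total expression, since transcripts left out of the table do not count. Transcripts that share a symbol were summed also where their gene IDs differ, as for COL15A1 and PDGFRA. Lists were fixed before the data were examined: 15 functional lists and 10 lists of cell type markers. A list's median log2 change was placed among 10000 random lists of the same size, matched in 20 bins of mean expression and drawn from the 1985 listed genes with at least 1 FPKM in the higher group. A measured member has a listed transcript and at least 1 FPKM in the higher group. Members that were not called are thus left out of the counts, and most listed transcripts pass the size rule. Percentiles are given for lists with at least 3 measured members. The genes of the table serve as their own background, so a percentile says nothing about genes outside it.

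Named genes were chosen by a rule fixed in advance: 14 genes of androgen response and adipocyte function where listed; for each list up to 2 members with the largest rise and up to 2 with the largest fall past the size rule; the 10 largest rises and 10 largest falls among genes with a symbol and at least 5 FPKM in the higher group; and the 5 largest rises and falls among lncRNAs and circRNAs. A few further list members and the circRNAs with the most reads were added after their values were seen, namely DGAT2, PLIN2, DCN, POSTN, COL14A1, NDUFS1, KRT8, MKI67, BUB1, circ_0007255, circ_0000013, circ_0005309, circ_0003828 and circ_0007293, as well as the neighbours of the lncRNAs. A few genes that meet the rule are not reported here, while the counts include them.

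The intervals and percentiles were tested on simulated data first. For circRNAs castrated against intact (7869 features), 200 circRNAs with at least 20 reads were changed by known folds in simulated counts. The interval lay apart from 1 in the true direction for 56.7% of 67 circRNAs changed 2-fold and for 100% of those changed 4-fold or 8-fold, and for 0.924% of unchanged circRNAs. For gene lists (1985 genes, 200 simulated lists of 10 members), 69% of lists shifted by 2 on the log2 scale lay at or above percentile 97.5. Of unshifted lists 4.5% lay outside percentiles 2.5 to 97.5. The changes were shuffled over all genes and the members drawn at random. These rates therefore do not hold for lists whose genes move together, or where direction depends on expression level. For the matrix genes, the heterogeneity statistic Q used in the closing observations passed its limit in 4.87% of 10000 simulated sets of 16 genes with a single true change. These sets were drawn without the filter on q-values, so they check the limit under its own assumptions and not for called genes. Q and its genes were chosen after the results were seen.

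Alternatives were another pseudocount, another FPKM minimum, a 1.5-fold or 4-fold rule, centring on the median, sums per gene, the highest transcript per gene, all listed members of a list, unmatched random lists and the authors' own calls. Intervals that hold jointly over all circRNAs and the table's own gene labels were added after the data were seen. Positions were not used here, since the tables' build and the names table's assembly differ. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.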

Results

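Backfat, the subcutaneous adipose tissue along the back, was compared between castrated and intact male Huainan pigs aged 300 days. Each group held 3 pigs and was represented by 1 sample and 1 value per transcript, so no spread between animals could be computed for any value. The mRNA table listed 2645 transcripts of 2266 gene identifiers, and the lncRNA table listed 18 transcripts, all with a q-value below 0.05 in the authors' deposited table. A gene missing from these tables is therefore not known to be unchanged. Counts of list members below cover called genes only and do not describe a whole list. The circRNA table listed 7869 circular RNAs with 46409 reads in the castrated group and 43589 reads in the intact group. The depth behind the FPKM values was not given in the sources used here. The study's title names fat deposition related to castration as its subject.

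Backfat of castrated pigs held higher levels of lipid-making and leptin transcripts, and lower levels of collagen and other matrix transcripts, than backfat of intact pigs. LEP (gene ID 396832), which encodes the adipocyte hormone leptin, stood at 49.6 FPKM in the castrated group and 1.93 FPKM in the intact group, 25.7-fold higher. ACACA (gene ID 397324), the acetyl-CoA carboxylase that starts fatty acid synthesis, was 8.10-fold higher, at 553 against 68.3 FPKM. COL1A1 (gene ID 397571), a chain of type I collagen, was 13.5-fold lower, at 581 against 7819 FPKM. SULT2A1, a steroid sulfotransferase, was 11.1-fold lower, at 4.92 against 54.5 FPKM.

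Of the 2645 listed transcripts, 1365 were higher and 1280 lower in the castrated group. A size rule of a 2-fold change on the log2(FPKM + 1) scale, with at least 1 FPKM in the higher group, was passed by 2181 transcripts, 1126 higher and 1055 lower. After centring on the median of the 1313 transcripts with at least 1 FPKM in both groups, a shift of 1.14 on the log2 scale, 133 were higher and 1146 lower. Summed per gene the shift was 0.47, and under it no named gene turned its direction, while PPARG, PLIN1, CKB, RGS5, CD2, EVPL and SRD5A2 no longer passed the rule. With a pseudocount of 5, the low genes PPARG, ALAS2, CD2, CDK1, DES, EGFL7, ETFDH, EVPL, ICAM1, IRS1, KLRK1, MMP9, SRD5A2, TCAP, TOP2A and TSC22D1 no longer passed, with a log2 change of 0.89 for PPARG. The list holds called transcripts only, so its median is no estimate of a scale difference. Fold changes below are ratios of FPKM summed over a gene's listed transcripts, and log2 values carry a pseudocount of 1, which understates the change of low genes.

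The called genes of fatty acid and triglyceride synthesis rose together. All 11 measured members, of 23 on the list, passed the rule upwards, with a median log2 change of 2.02. ACLY, the ATP citrate lyase that supplies cytosolic acetyl-CoA, rose from 95.6 to 1940 FPKM, and THRSP, a lipogenic nuclear protein, rose from 203 to 2339 FPKM. DGAT2, an enzyme of the last step of triglyceride synthesis, stood at 1210 against 358 FPKM. Macrophage, lymphocyte and erythroid markers were also higher in the same group, the erythroid gene HBB at 1383 against 130 FPKM. The median of the synthesis list lay at percentile 99.8 among 10000 random lists of the same size drawn from the listed genes and matched on expression, a description of these values and not a test.

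Called members of the other lipid lists also moved mostly upwards in the castrated group. These lists held 21 genes of lipolysis and lipid droplets, 25 of uptake and oxidation and 21 of cholesterol synthesis. In the lipolysis and lipid droplet list 8 of 9 measured members rose (median log2 1.72, percentile 94.9), among them the lipase gene PNPLA3 at 49.9 against 5.41 FPKM, MGLL at 445 against 74.2 FPKM and the droplet coat gene PLIN1 at 392 against 153 FPKM. PLIN2 passed in neither direction, at 10.5 against 10.1 FPKM, a sum over a transcript that rose from 2.82 to 10.5 FPKM and another that fell from 7.25 FPKM to a listed 0. By the highest transcript per gene PLIN2 rose too, giving 9 of 9. All 4 measured genes of fatty acid uptake and oxidation rose (median log2 1.46, percentile 93.5), including ETFDH at 6.34 against 0.686 FPKM and the fatty acid transporter CD36 at 29.2 against 8.74 FPKM. All 8 measured genes of cholesterol synthesis rose (median log2 1.60, percentile 94.1), including LSS, the lanosterol synthase, at 134 against 27.5 FPKM and the sterol sensor partner INSIG1 at 73.2 against 14.7 FPKM. After median centring 9 of the 11 synthesis genes, 6 of the 9 lipolysis and droplet genes, 4 of the 8 cholesterol genes and 2 of the 4 uptake and oxidation genes passed, and with a pseudocount of 5 also 2 of those 4. With random lists not matched on expression, the percentiles were 99.7 for lipolysis and lipid droplet and 98.5 for cholesterol synthesis.

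Called regulators and products of mature adipocytes were mostly higher in the castrated group, from lists of 26 regulators, 21 adipokines and 19 adipocyte markers. All 4 measured regulators of adipocyte differentiation rose (median log2 1.44, percentile 70.4), with PPARG, the main adipogenic nuclear receptor, at 13.0 against 4.71 FPKM, CEBPA at 246 against 81.1 FPKM and SFRP5 at 121 against 33.7 FPKM. Of 6 measured adipokines 4 rose and 2 fell (median log2 1.69, percentile 89.3). AGT, which encodes angiotensinogen, rose from 25.5 to 207 FPKM, while RARRES2, which encodes chemerin, fell from 72.1 to 21.8 FPKM and CFD, which encodes adipsin, fell from 236 to 79.5 FPKM. Among mature adipocyte markers 11 of 12 rose and CFD fell (median log2 1.61, percentile 90.8). Most of these markers also belong to the lipid, regulator, adipokine or glucose lists, and SFRP5 is both a regulator and an adipokine. The lists are therefore not independent of each other. After median centring 2 of the 4 regulators and 7 of the 12 adipocyte markers passed upwards, and with a pseudocount of 5 also 2 of the 4 regulators. Against random lists not matched on expression the percentiles were 90.4 for the regulators, 98.6 for the adipokines and 99.7 for the adipocyte markers.

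Called glucose and energy genes of the fixed lists mostly moved in the direction of the lipid genes. Their lists held 22 genes of insulin signalling and glucose uptake and 19 thermogenic and uncoupling genes. Of 10 measured genes of insulin signalling and glucose uptake, 8 rose and 2 fell (median log2 1.40, percentile 83.9). HK2, a hexokinase, rose from 7.21 to 84.2 FPKM and SLC2A4, the insulin-responsive glucose transporter, from 11.2 to 47.7 FPKM. PCK1 fell from 88.4 to 37.8 FPKM and IRS1 from 14.2 to 5.73 FPKM. All 3 measured thermogenic and uncoupling genes rose (median log2 1.38, percentile 80.9), with UCP3 at 80.3 against 23.3 FPKM and CKB at 62.7 against 23.4 FPKM. Of the fixed list of oxidative phosphorylation subunits NDUFS1 alone was listed, and it stayed below 1 FPKM in both groups and was not counted. After median centring 4 of the 10 insulin and glucose genes and 1 of the 3 thermogenic genes passed upwards. The percentile of the insulin and glucose list was 95.3 among lists not matched on expression. The KEGG insulin signalling pathway of the authors' table, looked at later, was less one-sided: 12 of 24 measured genes rose and 6 fell. Its median log2 was 0.65, against 1.04 over genes with a pathway, at percentile 21.25 of matched random sets. In KEGG glycolysis and gluconeogenesis 8 of 10 measured genes rose and 2 fell (percentile 75.1).

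Genes of steroid handling and androgen response, from lists of 29 and 28 genes, moved in both directions. Of 5 measured sex steroid genes 2 rose and 3 fell (median log2 -1.26, percentile 20.4). SULT2A1 fell from 54.5 to 4.92 FPKM and HSD11B1, which regenerates active glucocorticoid, fell from 118 to 27.7 FPKM. AKR1C4 rose from 171 to 588 FPKM, and SRD5A2, a steroid 5-alpha-reductase, stood at 1.65 against 0.311 FPKM. Of 4 measured androgen-responsive genes 1 rose, 2 fell and KRT8 passed in neither direction (median log2 -1.21, percentile 23.8). IGFBP3 fell from 49.6 to 6.04 FPKM, CAMKK2 fell from 23.3 to 8.04 FPKM and TSC22D1 rose from 0.468 to 3.32 FPKM. After median centring 1 of the sex steroid genes passed upwards and 3 of the androgen-responsive genes passed downwards, and with a pseudocount of 5 no androgen-responsive gene passed upwards. With a pseudocount of 0.1, 3 androgen-responsive genes passed downwards. Of the 14 genes named in advance for this question, ESR1, NR3C1, FKBP5, IGF1, ADIPOQ, FASN, SCD, LPL and LIPE had no listed transcript.

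Most called extracellular matrix genes fell. The matrix list held 32 genes and the list of fibroblast and progenitor markers 14. Of 17 measured members 15 fell and 2 rose, with a median log2 change of -2.11 and percentile 0.01. COL6A3 fell from 145 to 13.7 FPKM, DCN, which encodes the proteoglycan decorin, from 7677 to 911 FPKM, and POSTN, which encodes periostin, from 4615 to 464 FPKM. COL15A1, a basement membrane collagen, rose from 167 to 563 FPKM. This is a sum over 3 transcripts of separate gene IDs, the highest at 221 against 66.8 FPKM, and may overstate the gene's level. The gelatinase gene MMP9 stood at 4.996 against 0.0281 FPKM, near the floor of the intact group. All 3 measured fibroblast and adipocyte progenitor markers fell alongside (median log2 -1.65, percentile 14.5), with MFAP5 at 81.1 against 365 FPKM and PDGFRA at 67.1 against 213 FPKM. COL14A1 belongs to both of these lists. PDGFRA is likewise a sum over 2 transcripts of separate gene IDs. Among lists not matched on expression the percentile of the fibroblast and progenitor markers was 6.81.

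Called markers of other cell types also differed between the groups and did not move as a block. Their lists held 21 macrophage, 18 T and NK lymphocyte, 10 erythroid and 14 smooth muscle and pericyte markers. Members without a listed transcript were not counted. Macrophage markers rose in 3 of 3 measured members (median log2 2.98, percentile 99.5), with SPP1, which encodes osteopontin, at 154 against 7.64 FPKM and LYZ at 36.4 against 3.75 FPKM. T and NK lymphocyte markers rose in 4 of 4 (median log2 1.27, percentile 84.5), with KLRK1 at 7.96 against 2.16 FPKM and CD2 at 6.01 against 1.78 FPKM. Erythroid markers rose in 3 of 3 (median log2 1.94, percentile 96.5), and HBB, a globin gene of red blood cells, stood at 1383 against 130 FPKM with ALAS2 at 6.99 against 1.08 FPKM. Smooth muscle and pericyte markers fell in 5 of 6 (median log2 -1.48, percentile 9.21), with CNN1 at 3.89 against 15.1 FPKM and DES at 3.93 against 12.9 FPKM, while RGS5 rose from 46.5 to 130 FPKM. The skin markers went apart, EVPL at 1.47 against 0.171 FPKM and PPL at 3.60 against 26.1 FPKM (median log2 -0.74). Single measured members fell for skeletal muscle (TCAP, 1.32 against 4.76 FPKM) and endothelium (EGFL7, 4.48 against 13.1 FPKM). For B cells the single match was CR1, which the table labels CR2, at 0.628 against 11.7 FPKM. The B cell list holds CR2, matched by that label alone, so this fall may not be that of a B cell marker. After median centring 1 of the 4 lymphocyte markers and neither RGS5 nor EVPL passed upwards. With a pseudocount of 5, 1 of the 3 erythroid markers passed upwards and 3 of the 6 smooth muscle and pericyte markers downwards, and TCAP and EGFL7 did not pass. Against lists not matched on expression the percentiles were 97.9 for the erythroid and 5.30 for the smooth muscle and pericyte markers.

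Cell cycle genes of the fixed list rose in 7 of 9 measured members (median log2 1.21, percentile 88.9). Among them were the cyclin-dependent kinase gene CDK1 at 4.85 against 0.819 FPKM and TOP2A at 10.6 against 2.87 FPKM. MKI67, at 1.57 against 0.310 FPKM, and BUB1, at 1.60 against 0.368 FPKM, did not pass. With a pseudocount of 0.1 all 9 passed (median log2 1.84). In the KEGG cell cycle pathway of the authors' table, looked at later, 8 of 14 measured genes rose and 6 fell. Its median log2 of 1.04 lay at percentile 60.9 of matched random sets of genes with a pathway. Of 5 measured genes of inflammation and acute phase 3 rose and 2 fell (median log2 1.43, percentile 87.7). That list held 25 genes and the cell cycle list 26. The chemokine genes CXCL10, at 14.1 against 1.45 FPKM, and CXCL2, at 14.1 against 4.08 FPKM, rose, while the adhesion genes ICAM1, at 6.09 against 15.9 FPKM, and CD44, at 20.2 against 49.3 FPKM, fell. FOSL2 was the single listed immediate early gene and fell from 42.2 to 15.7 FPKM. With a pseudocount of 5 no cell cycle gene of the fixed list and no T and NK lymphocyte marker passed the rule, since these genes are low. After median centring 3 of the 9 cell cycle genes passed. The percentile of the cell cycle list was 79.4 among lists not matched on expression.

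**Figure D1:**
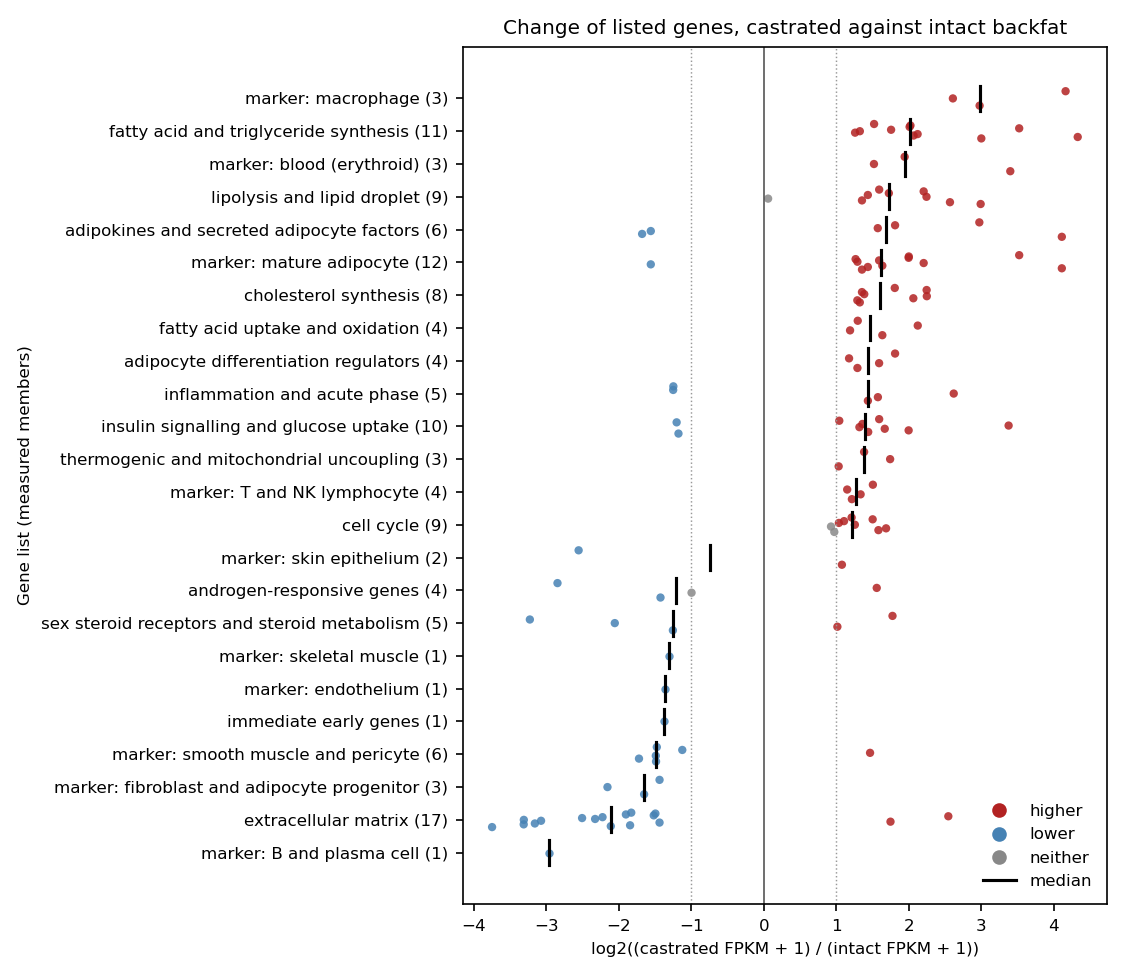
Each point is a measured gene of a list fixed before the data were examined, placed by its log2((castrated FPKM + 1) / (intact FPKM + 1)), with red for higher, blue for lower and grey for neither by the size rule (dotted lines at -1 and 1) and a black bar at each list's median. All 11 measured fatty acid and triglyceride synthesis genes lie on the higher side, and 15 of 17 measured matrix genes on the lower side.

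Over all named genes with at least 5 FPKM in the higher group, the 10 largest rises on the log2 scale included SPP1, ACLY and LEP. KLHL31 (gene ID 100152767), a kelch-like family gene, led them at 148 against 3.58 FPKM, 41.5-fold higher. KIAA0930 stood at 75.6 against 4.60 FPKM, the cell adhesion gene CADM2 at 58.9 against 3.47 FPKM and the metalloprotease gene ADAMTS18 at 21.1 against 0.745 FPKM. CALD1, which encodes the actin-binding caldesmon, was at 24.0 FPKM and ETNPPL, a phospholyase gene, at 11.0 FPKM in the castrated group, and both were listed at 0 in the intact group.

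The 10 largest falls were led by COMP (gene ID 396554), a cartilage matrix protein gene, at 0.531 FPKM in the castrated and 66.6 FPKM in the intact group. PAPPA2, a protease of IGF-binding proteins, stood at 1.07 against 72.2 FPKM, the complement gene C7 at 4.09 against 147 FPKM and the matricellular gene WISP2 at 0.910 against 45.3 FPKM. TNMD, which encodes tenomodulin, fell 25.6-fold, CLDN11, a claudin gene, 24.0-fold, and SPON1 19.6-fold. SAL1, which encodes a salivary lipocalin, fell from 123 to 7.06 FPKM, and AFF2 from 17.2 to 0.196 FPKM. In the authors' deposited table the q-value was listed at 0 for KLHL31, LEP, COMP and SAL1, and was 0.00317 for COL1A1, 0.00124 for ACACA, 0.0419 for PPARG and 0.0473 for PLIN1.

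**Figure D2:**
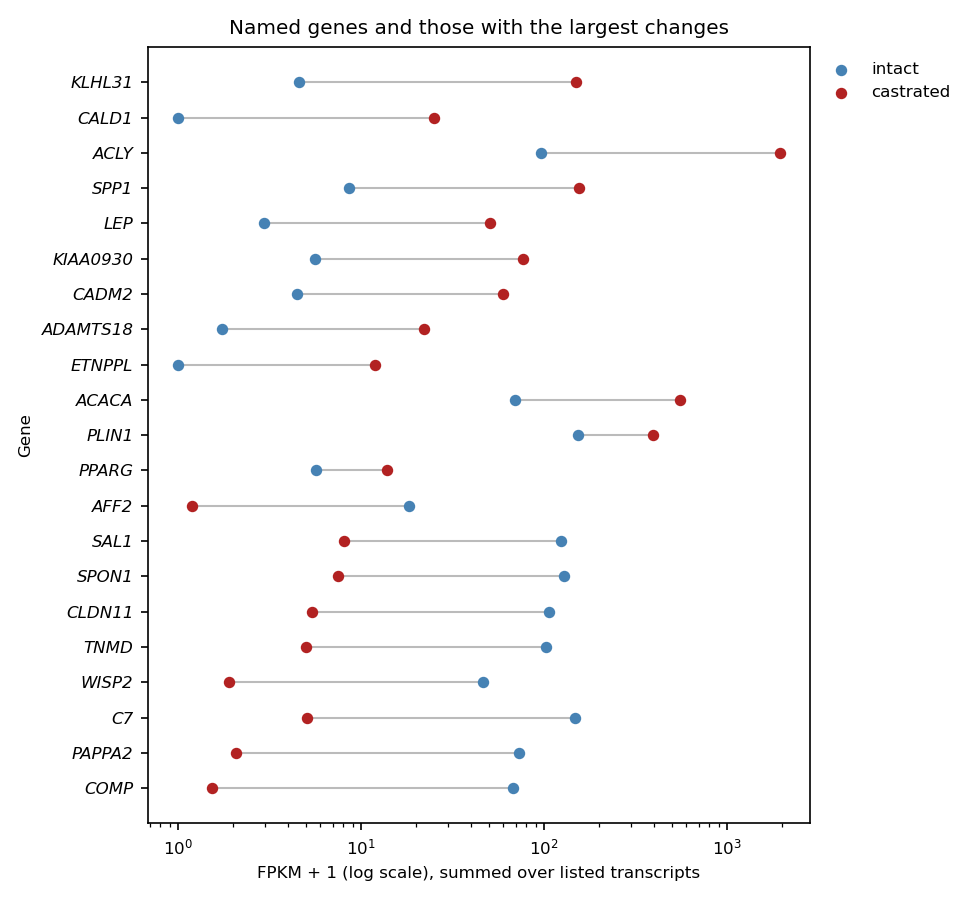
FPKM + 1 on a log axis, summed over listed transcripts, for the genes named in advance and those with the largest rises and falls that are reported here; blue points are the intact group, red points the castrated group, and a line joins the 2 values of a gene. KLHL31 at the top rose from 3.58 to 148 FPKM and COMP at the bottom fell from 66.6 to 0.531 FPKM.

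Long noncoding RNAs were compared in the same way, and the largest rise lay beside ACACA. TCONS_00392681 stood at 15.4 FPKM in the castrated and 1.25 FPKM in the intact group, 12.3-fold higher, and the authors' deposited table named ACACA, itself 8.10-fold higher, among its neighbouring target genes. TCONS_00465264 fell from 15.98 to 3.96 FPKM beside COL6A6, a collagen VI gene that fell from 89.0 to 26.2 FPKM. Of the 18 listed lncRNAs 9 were higher and 9 lower, and 12 passed the size rule, 7 higher and 5 lower. After centring on the median of those with at least 1 FPKM in both groups, 1 was higher and 9 lower, a median that rests on 7 lncRNAs.

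The other lncRNAs with the largest rises were TCONS_01757189 at 14.9 against 2.57 FPKM, TCONS_01199263 at 11.3 against 2.62 FPKM, TCONS_01075956 at 144 against 41.9 FPKM and TCONS_01876341 at 3.14 against 0.571 FPKM. The other falls past the rule were TCONS_01668288 at 1.504 against 6.61 FPKM, TCONS_00625772 at 0.277 against 2.23 FPKM, TCONS_00784934 at 0.983 against 3.48 FPKM and TCONS_01646544 at 0.996 against 3.02 FPKM. The authors' table gave neighbouring genes for 13 of the lncRNAs, and 6 lncRNAs had a neighbour with a listed mRNA transcript, forming 11 pairs. In 7 pairs both moved in the same direction and in 4 they moved apart. TCONS_01075956 rose with COL5A3, at 175 against 53.7 FPKM, while its other listed neighbour OLFM2 fell, at 0.381 against 2.19 FPKM. TCONS_01199263 rose while both listed transcripts of PCOLCE, a procollagen processing enhancer gene, fell, from 40.3 to 5.67 FPKM and from 197 to 70.1 FPKM, and SAP25 rose, at 1.92 against 0.459 FPKM. The pairs were drawn from called transcripts only and are not independent of each other.

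Circular RNAs, closed loops formed by back-splicing, were counted in reads, which gives each ratio a counting interval. The circRNA with the most reads in the castrated group, circ_0007255, had 1515 reads there and 110 in the intact group, a share of circRNA reads 12.9-fold higher (exact 95% interval 10.7 to 15.8). By the same count circ_0000013 had 1103 against 295 reads (ratio 3.51, 3.09 to 4.01). Next came circ_0005309 with 989 against 455 reads (ratio 2.04, 1.83 to 2.29) and circ_0003828 with 913 against 216 reads (ratio 3.97, 3.42 to 4.63). The circRNA with the most reads in the intact group, circ_0007293, had 742 reads in the castrated and 1061 in the intact group (ratio 0.657, 0.597 to 0.722). These intervals cover counting error only and compare the values of the 2 groups as deposited, not the conditions.

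Of the 7869 circRNAs, 4982 had reads in the castrated and 5244 in the intact group, and 2357 had reads in both (29.95%, Wilson 95% interval 29.0 to 31.0). A total of 2 reads was all that 44.7% of them had, and no value of 1 read was listed, so a listed 0 may stand for a single read. The smallest count above 0 was 2, so a circRNA with a total of 2 or 3 reads could not appear in both groups. The median total was 3, so the share seen in both groups was set in large part by this cutoff, which its interval does not cover. At the level minimum of 64.6 reads per 1000000 circRNA reads, 1022 of 4172 circRNAs passed the 2-fold rule upwards and 1309 downwards. The exact 95% interval of the ratio lay above 1 for 282 circRNAs and below 1 for 374. With intervals widened to hold jointly over all listed circRNAs, a choice made after the data were seen, 33 lay above 1 and 28 below. The 10 highest circRNAs held 15.9% of reads in the castrated group (Wilson 95% interval 15.5 to 16.2) and 10.01% in the intact group (9.74 to 10.3).

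Several circRNAs had many reads in a single group. Against a floor of 3 counts for a value of 0, circ_0006268, with 275 reads in the castrated group, was at least 86.1-fold higher there, circ_0005634 with 136 reads at least 42.6-fold, circ_0006283 with 96 reads at least 30.1-fold, circ_0006270 with 53 reads at least 16.6-fold and circ_0006279 with 32 reads at least 10.02-fold. The floor counts error in the value of 0 alone, and the exact 95% lower limits of these ratios, which also count error in the reads seen, were 69.6, 34.2, 24.0, 13.0 and 7.69. Floor and limits both take a listed 0 as no read. In the other direction circ_0007741, with 98 reads in the intact group, was at least 34.8-fold lower in the castrated group, circ_0006278 with 36 reads at least 12.8-fold, circ_0006918 with 32 reads at least 11.4-fold, circ_0005011 with 28 reads at least 9.94-fold and circ_0003405 with 24 reads at least 8.52-fold, with exact 95% lower limits of 27.8, 9.87, 8.71, 7.56 and 6.41. Host genes and positions of the circRNAs were not analysed here, so they were not set against the mRNAs of their genes.

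**Figure D3:**
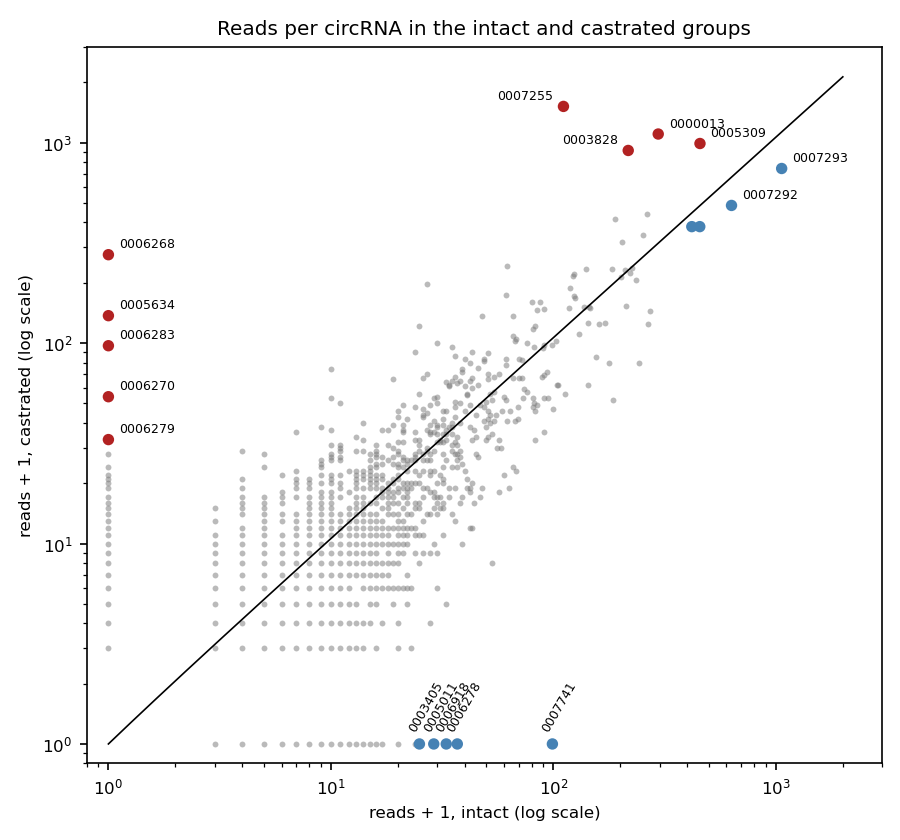
Reads + 1 per circRNA on log axes, intact group on the horizontal and castrated group on the vertical axis; grey points are pairs of counts found in the table, coloured points are the circRNAs with the largest changes or most reads (red higher, blue lower in castrated), and the line marks equal shares of the 46409 and 43589 reads. circ_0007255 lies far above the line at 1515 against 110 reads, and circ_0006268 lies on the left edge at 275 against 0.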

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

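The joint circRNA intervals and the table's own gene labels were chosen after the data were seen. Of the listed mRNA transcripts 2181 passed the size rule (51.6% of them higher). With a pseudocount of 5, 882 passed (55.6% higher); with a minimum of 5 FPKM, 1323; with a 4-fold rule, 388 (47.2% higher); and after median centring, 1279 (10.4% higher). Of the lncRNAs 12 passed, against 5 with a pseudocount of 5, 6 with a minimum of 5 FPKM and 2 with a 4-fold rule (100% higher); after centring 10% of those passing were higher. Of the circRNAs 2331 passed, against 56 with a pseudocount 10 times larger (51.8% higher), 5846 without a minimum (46.9% higher), 383 with a 4-fold rule and 61 with joint intervals (54.1% higher). A stricter rule or larger pseudocount keeps fewer features by construction; for the changes in the shares the cause was not tested, apart from centring of the mRNAs and lncRNAs, which lowers every log2 value of a table by the same amount. Of 143 list medians under alternatives 32 moved, 13 of them after centring, and of 19 list percentiles 11 moved with unmatched random lists. Under each of the 6 alternatives that can change a median, 14 lists had a median above 0. No list median or named gene turned its direction, with genes centred by 0.47. The shift of 1.14 found over transcripts was not applied to genes, and it exceeds the log2 changes of SRD5A2 (1.01) and EVPL (1.08). Of 300 values of named genes under alternatives, 276 stayed past the rule and 24 fell below it, 17 with a pseudocount of 5 and 7 after centring. No paired analysis was possible because each group has a single value. Left-out pigs, circRNAs summed per host gene, the authors' circRNA calls and circRNAs against host mRNA were not run, since values per pig, host genes and circRNA calls were not used here. Depth limits the circRNAs, of which 44.7% rest on 2 reads.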

Other observations

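All tests in this part, and the genes it names, were chosen after the results were seen. By the KEGG pathways that the authors' table assigns, genes of the complement and coagulation cascades were lower in castrated backfat: 14 of 15 measured genes fell and KLKB1 rose (median log2 -1.59). C7 showed the deepest fall, and C9 fell from 144 to 34.7 FPKM, C1R from 222 to 70.6 FPKM, the C1 inhibitor gene SERPING1 from 218 to 66.6 FPKM and C2 from 50.4 to 14.9 FPKM. CFD and CR1, which also stand in other lists, belong to this pathway. Its median lay at percentile 0.45 among 2000 random sets matched on expression. Of 119 pathways with at least 10 measured genes, 10 lay in the lowest 2.5% of random sets and 2 in the highest 2.5%, against 2.98 expected at each end, and the pathways share genes. Lower than the complement set lay PI3K-Akt signalling (percentile 0), focal adhesion (0.1), Ras signalling (0.15) and ECM-receptor interaction (0.2). Protein digestion and absorption and proteoglycans in cancer (both 0.35) also lay lower. At the high end stood metabolic pathways (99.2, 110 of 159 genes higher and 42 lower) and purine metabolism.

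In purine metabolism 16 of 22 measured genes rose and 6 fell (median log2 1.41, percentile 98.55); since no more pathways stood at the high end than chance gives, this is a description of those genes and does not set the pathway apart. AK4, a mitochondrial adenylate kinase gene, rose from 85.2 to 290 FPKM, PDE3B, the insulin-regulated phosphodiesterase gene, from 23.0 to 71.2 FPKM and PKM, a pyruvate kinase gene, from 11.0 to 35.0 FPKM, while ADCY2, an adenylyl cyclase gene, fell from 11.8 to 1.88 FPKM. Among the most abundant transcripts rises were more common: of 199 transcripts with at least 100 FPKM in the higher group 63.3% were higher in castrated backfat (Wilson 95% interval 56.4 to 69.7), against 47.4% of 677 with 3 to 10 FPKM (43.7 to 51.2). The share was 49.1% at 1 to 3 FPKM, 49.7% at 10 to 30 FPKM and 56.2% at 30 to 100 FPKM (50.8 to 61.5), which overlaps the top level. Transcripts are not independent replicates.

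Adipocyte genes were higher and matrix genes lower in the castrated group, and tissue makeup or scaling could account for part of this. A single scale factor between the groups, with no other change, would move nearly all transcripts one way, and 51.6% of the listed ones were higher. Uncalled transcripts are not listed, so a scale factor on top of other changes stays open. A larger share of adipocytes that lowers every other cell type alike would give the markers of other cell types a common fall. Of the 24 listed markers 12 rose, so these did not share in such a fall, and 12 fell. Their heterogeneity Q was 528 (limit 35.2, and 457 without SPP1). Its errors are implied by the authors' p-values and may leave out the spread between pigs. Only called markers are listed, so with both directions present a high Q was close to fixed in advance. Mature adipocyte markers alone also passed the limit, with 96.2 (limit 19.7) and 36.9 without CFD (limit 18.3). Q thus decides nothing on the shares of cell types. A uniform fall in the share of matrix-producing cells cannot be told apart from a lower expression per cell: without MMP9, which is near the floor, Q was 95.8 (limit 24.996), but without COL15A1 too it was 21.95 (limit 23.7). An effect of castration itself and differences between the pigs stay open, untested.

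In 110 gene IDs, listed transcripts went in opposite directions, as in RORA, where a transcript stood at 11.8 against 5.03 FPKM and another at 0.00709 against 11.4 FPKM. Reads shifted between transcripts of the same gene, by the assignment of shared reads or by a change of isoform, would keep the summed FPKM alike. On the log2(FPKM + 1) scale the sums differed by less than 2-fold in 80.9% of these gene IDs. Plain ratios of low sums can be larger, as in GPAT3, counted here at 1.54 against 4.05 FPKM. On the same scale, transcripts of other genes matched in level and direction gave 78.2% (95% of 10000 draws between 72.7 and 83.6). The sum therefore decides nothing, and a misassignment of reads cannot be told apart from a change of isoform.

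Between circ_0006263 and circ_0006283, 21 consecutive identifiers, lay 7 of the 31 circRNAs that had at least 15 reads in a single group and none in the other, 5 of them in castrated and 2 in intact backfat. A chance order of the identifiers gave at most 5 in any window of 25 in 100000 permutations (p = 1e-05, the smallest they can give). The permutations used all identifiers, although 44.7% of circRNAs had a total of 2 reads and could not reach the minimum. They therefore cannot tell a clustering of one-sided circRNAs from a clustering of circRNAs with many reads. The run held 794 against 210 reads, a ratio of 3.55 (exact 95% interval 3.05 to 4.15), or 2.32 (1.97 to 2.74) without circ_0006268 and 1.56 (1.28 to 1.92) over the 5 circRNAs seen in both groups. Reads assigned to different neighbouring identifiers would leave this sum alike, but the run was picked for its one-sided circRNAs and a difference in level can add to such a shift, so the 2 cannot be told apart. What the order of identifiers means was not given, and a difference between the pigs' genotypes and an effect of castration stay open, untested.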
